A study of Mus musculus with 6 samples.

How the data were processed

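RNA was measured in GFP-positive cells sorted from the heads of mouse embryos at embryonic day 9.5. Per the labels' treatment protocol, cranial neural crest came from Wnt1-Cre x Z/EG embryos and cranial mesoderm from Mesp1-Cre x Z/EG embryos, and the series design gives 3 independently isolated replicates of each. Per the labels' extraction and labelling protocols, RNA was taken up on micro columns, amplified with a TotalPrep kit and labelled with biotin as cRNA, then hybridized to Illumina mouse whole-genome arrays. The amplification starts at the poly(A) tail, so transcripts without one are measured poorly. The scanner settings, the summary software and the way replicates were isolated (litter, day, number of embryos) are not given in the sources used here. The label of each array places all 6 on 1 BeadChip, the crest arrays at the first 3 positions and the mesoderm arrays at the last 3, so that position on the chip cannot be told apart from cell type.

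The deposited table of raw values gives, for 45281 probes and each array, a linear signal intensity without background subtraction or scaling between arrays. Beside each signal it gives a detection p-value, deposited as the rank of the probe among the array's negative controls. The deposited series matrix gives log2 values from the authors. Each of its sorted columns equalled the mean of the 6 sorted log2 signal columns to within 0.00571, so the authors' log2 values are the same signals after quantile normalization without background subtraction. They were used as an alternative only.

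The deposited detection p-values did not all go with the signal on their line. A detection p must fall as the signal on its array rises, yet in 12276 probes (27.1%) it lay more than 0.06 from the running median of 101 probes ranked by signal. Of 5306 such probes whose expected p lay between 0.1 and 0.95, 5300 had a probe within 12 lines of the table whose signal gave their p to within 0.02. Both probes belonged to the same gene in 4477 cases, to different genes in 14, and in the rest 1 probe (252 cases) or both (557 cases) had no gene name. Among genes with 1 probe 1% of lines were affected, and among genes with more probes 42.9%. Whether the signal or the p carried the wrong probe could not be told. Where both probes share a gene, a value is therefore that of a gene and not of a particular probe. The tracing asked for an expected p over 0.1 on every array, while a tested probe needed a detection p under 0.05. It therefore covered probes that were not tested. Of the 1702 genes called different below, 397 were read from a line whose p did not go with its signal. Whether those signals stayed within the gene was not checked. The 14 traced to different genes were left out. The detection p was re-read from each array's own signals by this running median, and the deposited p was kept as an alternative. The procedure was tested on simulated data in which 6470 lines took the p of a neighbour by more than the tolerance could hide: 100% of them were found and 0% of the others were marked.

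Probes were matched to genes by the table supplied for the array, in which 34885 probes had 1 symbol, 18 had several and 10378 had none. Probes of the last 2 kinds were not tested. A comparison with a current annotation by gene number changed 0 of 34807 symbols. Positions in the genome are not given, since the annotation at hand gives only names.

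Signals were background-corrected with the normal-exponential model of limma 3.58.1 in R 4.3.3, its background taken from the detection p-values. An offset of 16 was added before quantile normalization and log2. A probe was kept when its detection p was under 0.05 on at least 3 of the 6 arrays, and 15212 named probes were. Each gene was represented by its kept probe with the highest mean log2 value, which left 9218 of 19053 genes for testing. limma's linear model with its empirical Bayes variance compared mesoderm with crest, 3 arrays against 3, with no other term. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. A log2 difference is mesoderm minus crest, with the standard error from the moderated variance. For a gene detected on no array of the lower group, the fold is a lower bound: the mean of the higher group against a mean in which each array of the lower group stands at its lowest detected log2 value, or at its own value where that is higher. A gene detected on only some arrays of the lower group has no bound, and its difference rests partly on values near background. Medians of lists are given with such genes at their bound where that moves them.

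Before the data were examined, 28 gene lists, the tests and the rule for naming genes were fixed. The lists cover cell types that either sort could hold, signalling pathways, adhesion, stress and cell cycle. Of their 338 tested entries, 1 gene stood in more than 1 list. List members that did not pass the detection filter were not tested, so counts over tested members leave out undetected genes of the same kind. A list with at least 4 tested members (27 lists) was compared with all other genes by camera with a preset correlation of 0.01 between genes, adjusted over the lists. An alternative estimated the correlation within each list, and fry tested each list by itself. Counts of members are given from the adjustment over all genes and from that over the list alone. The rule named the 10 genes with the largest fold in each direction among those past the threshold whose arrays did not overlap between groups. A gene with a lower bound was ranked by that bound. The rule also named up to 4 members per list with the smallest adjusted p. It added up to 2 more past the threshold against the list's majority, and 14 genes fixed by name. Genes outside it are said to be so where they are named.

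Alternatives fixed with the design were no background correction, an offset of 50, median scaling, the authors' values, no detection filter, a stricter filter (detection p under 0.01 on all 3 arrays of a group), the mean of a gene's probes, the replicate number as a block, array weights, a variance prior with trend and robust fitting, a minimum fold of 2, an adjusted p under 0.01, list members detected in both groups, and each array left out in turn. Alternatives added after the data were seen were the deposited detection p, only probes whose deposited p went with their signal, and both replicate 2 arrays left out, with the filter applied anew and with the same genes tested.

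The arrays hold no counts, so their number and the background limit the precision. In a self-test, known changes were put into 200 of 11946 genes of arrays built from these values: 9 of 67 genes changed 2-fold were recovered (13.4%), 50 of 67 changed 4-fold (74.6%) and 64 of 66 changed 8-fold (97%). Of the 124 calls, 1 was an unchanged gene. Differences near 2-fold were therefore mostly missed in the self-test. It changed a smaller share of genes than the 18.46% called in the data, and its noise was independent between genes. These rates need not carry over to the data.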

Results

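Expression was measured on 6 arrays, 3 of cranial neural crest and 3 of cranial mesoderm, from heads of mouse embryos at embryonic day 9.5. Both populations were sorted by a GFP reporter switched on by a Cre recombinase. Wnt1-Cre marks the dorsal neural tube and midbrain and the crest cells that leave them, and Mesp1-Cre marks early mesoderm and its descendants, among them head mesenchyme, muscle, vessels and heart. Of 45281 probes, 33.0%, 34.1% and 32.0% were detected on crest replicates 1, 2 and 3, and 32.2%, 32.6% and 30.9% on mesoderm replicates 1, 2 and 3. The median signal lay between 99.8 and 131 intensity units, and the fitted background mean between 97 and 124. Pearson's r of log2 values across probes, which are not independent replicates, was 0.9603 to 0.9868 among crest arrays, 0.9495 to 0.9686 among mesoderm arrays and 0.8381 to 0.9102 between the groups. No pair of arrays had an identical signal at more than 1 of the 45281 probes. All arrays lay on 1 BeadChip with the groups at separate positions, so within-batch values cannot be given.

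The comparison asked which transcripts distinguish cranial mesoderm from cranial neural crest, in a series whose title concerns targets of TWIST1 in the mesoderm. TWIST1 is a basic helix-loop-helix factor of head mesenchyme. Toward mesoderm, Pf4, platelet factor, was at least 138-fold higher than in crest, the endothelial sialomucin gene Emcn at least 112.9-fold and the adhesion gene Icam2 at least 84.3-fold. Esam, an endothelial junction gene, was higher by 7.44 ± 0.22 on the log2 scale (SE, n = 3 per group), the apelin receptor gene Aplnr by 6.92 ± 0.32 and Cldn5, of endothelial tight junctions, by 6.86 ± 0.29. Esam and Aplnr were each detected on 1 of the 3 crest arrays, so their differences rest partly on values near background. Toward crest, En1 and En2, homeobox genes of the midbrain-hindbrain region, differed by -5.80 ± 0.41 and -5.32 ± 0.40, the dorsal neural tube ligand gene Wnt3a by -5.29 ± 0.30, and the crest factor genes Sox10 and Tfap2b by -4.94 ± 0.36 and -4.73 ± 0.42. En1, En2 and Wnt3a were each detected on 1 of the 3 mesoderm arrays, and the same limit holds for them.

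Of 9218 genes tested, 935 were higher in mesoderm and 767 in crest at an adjusted p under 0.05 by limma, and 810 and 552 of these differed at least 2-fold. In 3432 genes (37.2%) the arrays of the groups did not overlap, against 10% by chance. The other genes with the largest folds toward mesoderm were Klhl6 (at least 64.3-fold), a gene of lymphoid cells, Treml1 (at least 48.9-fold), a platelet receptor gene, Sox18 (at least 48.7-fold), an endothelial factor gene, and Gimap1, a GTPase gene of lymphocytes, with a log2 difference of 5.68 ± 0.23. Without mesoderm replicate 1, 2 or 3 another probe of Gimap1 became its brightest and gave 2.22, 2.74 and 2.71, while the first probe gave 5.65 to 5.76. Toward crest they were the noncoding Miat at -5.73 ± 0.74, the hormone precursor gene Trh (at least 19.1-fold), the neural factor gene Sox21 at -4.34 ± 0.58, 2700046A07Rik at -4.28 ± 0.29 and the splicing factor gene Hnrnpa1 at -4.28 ± 0.52. Genes ranked by a bound may stand too low in this order, such as Dlx1, at least 14.4-fold higher in crest with a fitted difference of -4.53. Hnrnpa1 has many near-identical copies in the genome, and without crest replicate 2 its brightest probe was another, which gave -1.52 (adjusted p = 0.0691, call lost), the first probe giving -3.92. The counts changed with settings, and both fell in every fit with 1 array left out. Such a fit has 2 arrays in 1 group and 3 in the other, and so less power. A lower count or a lost call there does not by itself show dependence on that array. Which sort had more genes also changed with the setting and with the array left out. Crest had more under median scaling (726 against 596) and array weights (1470 against 1310), and without mesoderm replicate 2 (735 against 649) or 3 (575 against 561). The mesoderm count was 433 without mesoderm replicate 1, 561 without mesoderm replicate 3 and 623 without crest replicate 3. The crest count was 437, 379 and 241 without crest replicates 1, 2 and 3, and 378 without mesoderm replicate 1. A gene detected in 1 group alone drops out of the tests when an array of that group is left out, since the filter asks for 3 arrays.

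**Figure D1:**
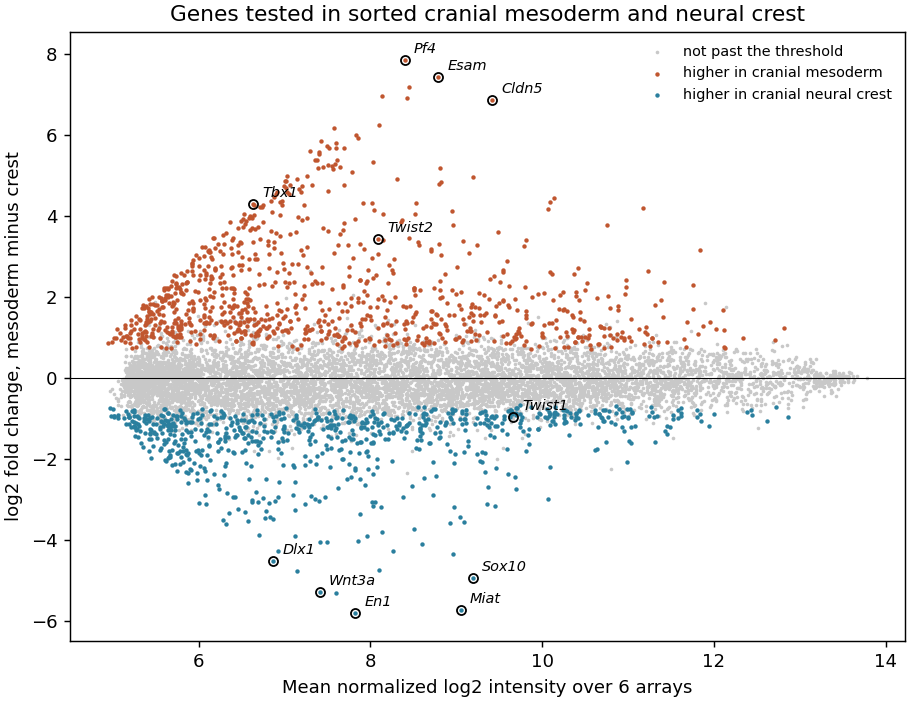
Mean normalized log2 intensity over the 6 arrays (x) against the log2 difference, mesoderm minus crest (y), for the 9218 genes tested, 1 point per gene. Coloured points are the 935 genes higher in mesoderm and the 767 higher in crest. Labelled genes are given in the text, with Twist1 not past the threshold.

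Endothelial genes rose together in the mesoderm sort. Of 23 tested, 22 were higher and 0 lower (22 and 0 adjusted over the list alone), with a median log2 difference of 4.26 (3.98 with 10 members at their bound, camera adjusted p = 6.06e-29). Beyond Esam, Emcn, Icam2 and Sox18, the junction gene Pecam1 was at least 10.1-fold higher. Without mesoderm replicates 1, 2 and 3 in turn 11, 11 and 12 members were past the threshold, since members seen in mesoderm alone were no longer tested. The exception was Kdr, the main VEGF receptor gene, at -0.11 ± 0.24 (adjusted p = 0.81), measured by 1 kept probe near background. The list of macrophages and other white cells, which also holds platelet genes, had 14 of 15 members higher in mesoderm (15 adjusted over the list alone), with a median of 3.07 (2.60 with 12 at their bound, adjusted p = 5.57e-16). Besides Pf4, the platelet integrin gene Itga2b was at least 37.1-fold higher, the lysozyme gene Lyz1 at least 9.25-fold and the complement gene C1qb at least 8.43-fold. For the same reason its count was 2, 3 and 2 without mesoderm replicates 1, 2 and 3.

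Red cell genes rose as well, 9 of 13 being higher in mesoderm and 0 lower (12 and 0 adjusted over the list alone), with a median of 3.38 (adjusted p = 4.35e-08, adjusted p = 0.176 with an estimated correlation). The blood factor genes Lmo2, Nfe2 and Tal1 were among them, Lmo2 by 4.85 ± 0.22, Nfe2 at least 17.7-fold and Tal1 at least 11.8-fold, and Cited4 rose by 2.94 ± 0.35. The count was 2, 4 and 2 without mesoderm replicates 1, 2 and 3 and 5 without crest replicate 3. The globin Hbb-bh1, named after its values were seen, was higher in mesoderm (adjusted p = 0.0487) over very unequal crest arrays. It stood at 11.28, 5.50 and 10.46 log2 units on crest replicates 1, 2 and 3 and at 13.25, 13.08 and 13.50 on the mesoderm arrays.

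**Figure D2:**
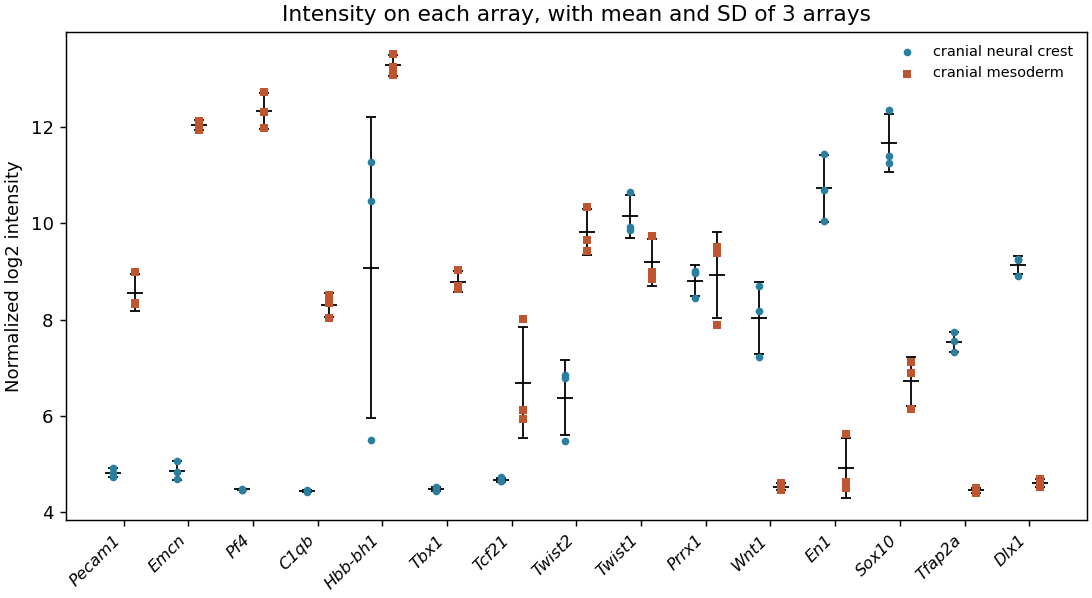
Normalized log2 intensity (y) of 15 genes (x) on each of the 3 crest and 3 mesoderm arrays, 1 point per array, with the group mean and SD as bars. Hbb-bh1 stood at 5.50 on crest replicate 2 and at 10.46 or more on the other 5 arrays.

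Genes of head mesoderm itself were also higher in the mesoderm sort. In the list of cranial paraxial mesoderm and head muscle progenitors 7 of 9 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 2.03 (adjusted p = 1.3e-06). Tbx1, a T-box gene of pharyngeal mesoderm, was at least 11.9-fold higher, and the bHLH genes Msc, Twist2 and Tcf15 were higher by 3.65 ± 0.33, 3.43 ± 0.41 and 2.66 ± 0.32. Tcf21, a marker of head muscle progenitors, was at least 2.77-fold higher (adjusted p = 0.0225), a call lost without crest replicate 1, 2 or 3 (adjusted p up to 0.0795). It was also lost without background correction (0.82, adjusted p = 0.104), with the authors' values (0.89, adjusted p = 0.0912), with an offset of 50 and with no filter. Of 20 heart field and heart muscle genes on the array, 9 passed the detection filter. Nkx2-5, Gata4, Tbx5, Myl7, Myh6, Myh7 and Nppa were among those that did not. Of the 9, 6 were higher in mesoderm and 0 lower (8 and 0 adjusted over the list alone), with a median of 1.57 (camera adjusted p = 3.31e-06). The atrial myosin light chain gene Myl4 was higher by 2.56 ± 0.24, the cardiac actin gene Actc1 at least 5.06-fold, the factor gene Gata6 at least 3.56-fold and Fgf10, a second heart field ligand gene, by 1.68 ± 0.32. Without mesoderm replicates 1, 2 and 3 the heart count was 2, 3 and 3. Mesp1, whose locus drives the Cre, was detected on 0 of the 6 arrays.

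Matrix genes followed the same direction, with 14 of 28 higher in mesoderm and 1 lower (16 and 1 adjusted over the list alone), and a median of 1.03 (0.89 with 3 at their bound, adjusted p = 3.31e-06, adjusted p = 0.0807 with an estimated correlation). Col4a1 and Nid1, of basement membranes, rose by 2.43 ± 0.22 and 1.85 ± 0.22, the cartilage link protein gene Hapln1 by 1.70 ± 0.22, and the proteoglycan gene Dcn was at least 3.09-fold higher. The collagen receptor genes parted. Ddr2 was at least 1.64-fold higher in mesoderm (adjusted p = 0.012), a call lost without background correction (adjusted p = 0.065), with the authors' values (0.0586) and under median scaling (0.0531), and Ddr1 was lower at -1.27 ± 0.30, a call lost without crest replicate 1, crest replicate 3 or mesoderm replicate 1 (adjusted p up to 0.0938). Pcolce, a collagen-processing enhancer, differed by 0.74 ± 0.41 (adjusted p = 0.254), by 0.30 without mesoderm replicate 2 and by 1.14 without mesoderm replicate 3. Genes of dissociation and stress were also higher in mesoderm, 8 of 16 and 0 lower (10 and 0 adjusted over the list alone), with a median of 1.01 (0.76 with 3 at their bound, adjusted p = 8.1e-05, adjusted p = 0.176 with an estimated correlation). Fos, an immediate early gene, was at least 6.07-fold higher, and Zfp36 and Ier3, early response genes, rose by 1.95 ± 0.23 and 1.85 ± 0.28. Gadd45b was at least 1.48-fold higher, a call lost without crest replicate 1 (adjusted p = 0.0507). The stress count was 4 without crest replicate 2, 2 without mesoderm replicate 1 and 4 without mesoderm replicate 3.

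In the crest sort the clearest group was that of the neural tube and midbrain. Of 15 genes tested 14 were higher in crest and 0 in mesoderm (14 and 0 adjusted over the list alone), with a median of -2.58 (adjusted p = 1.24e-10). Beside En1, En2 and Wnt3a, the forebrain and midbrain gene Otx2 differed by -3.57 ± 0.32, and Wnt1, whose enhancer drives the Cre, was at least 6.73-fold higher in crest. The count was 9 without crest replicate 1 and 9 without crest replicate 3. Migratory crest genes gave 5 of 11 higher in crest and 1 in mesoderm (6 and 1 adjusted over the list alone), with a median of -1.02 (adjusted p = 0.00179, adjusted p = 0.0807 with an estimated correlation). Besides Sox10 and Tfap2b, Tfap2a, needed for crest induction, was at least 4.77-fold higher in crest, and the endothelin receptor gene Ednrb differed by -2.69 ± 0.27. Snai2, a repressor of epithelial genes, went the other way at 0.88 ± 0.23, but its call was lost on leaving out any of the 6 arrays (adjusted p up to 0.143). The count of migratory genes higher in crest was 3 without crest replicate 1 and 3 without crest replicate 3. Foxd3, an early crest factor gene, was detected on 0 of the 6 arrays.

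The distal-less genes Dlx1, Dlx2 and Dlx6 of the pharyngeal arches were detected on every crest array and on no mesoderm array. Of 16 pharyngeal arch patterning genes on the array, 6 were tested, and Dlx4, Dlx5, Hand1 and Hand2 were among those that failed the filter. Of the 6, 4 were higher in crest and 0 in mesoderm (4 and 0 adjusted over the list alone), with a median of -2.18 (-1.82 with 3 at their bound, camera adjusted p = 2.82e-04, adjusted p = 0.0739 with an estimated correlation). Dlx1 was at least 14.4-fold higher in crest, Dlx2 at least 7.51-fold and Dlx6 at least 3.69-fold. Dlx3, detected on all 3 mesoderm arrays, differed by -1.76 ± 0.48, a call lost on leaving out any array but crest replicate 2 (adjusted p up to 0.126). The arch count was 0, 1 and 0 without crest replicates 1, 2 and 3, where Dlx1, Dlx2 and Dlx6 were no longer tested. Of 14 genes of sensory and autonomic neurons on the array, 5 were tested, and Neurog1, Neurod1, Pou4f1 and Tubb3 were among those that failed the filter. All 5 were higher in crest (5 adjusted over the list alone), with a median of -2.27 (-1.76 with 3 at their bound, camera adjusted p = 1.81e-04, adjusted p = 0.176 with an estimated correlation). Stmn2 and Elavl3, of young neurons, differed by -3.03 ± 0.54 and -2.94 ± 0.40, the migration gene Dcx was at least 3.39-fold higher and the autonomic factor gene Phox2a at least 2.54-fold. The neuron count was 2 without any 1 of the crest arrays. Of 5 glia and pigment genes 1 was higher in crest and 0 in mesoderm (3 and 0 adjusted over the list alone), with a median of -0.77 (-0.58 at the bound, adjusted p = 0.0379, adjusted p = 0.176 with an estimated correlation). That gene was Gfra3, a receptor of the GDNF family, at least 1.49-fold higher. The list's call was also lost without background correction (median -0.42), with an offset of 50 (-0.65), the authors' values (-0.47), the mean of a gene's probes (-0.77) or members detected in both groups (-0.55), under median scaling (-0.96) and without crest replicate 3, mesoderm replicate 1 or mesoderm replicate 2 (medians -0.56, -0.79 and -0.98).

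Twist1 was abundant in both sorts. Its log2 level was 10.15 ± 0.44 in crest and 9.19 ± 0.48 in mesoderm (SD, n = 3 each), a difference of -0.96 ± 0.32 (SE, adjusted p = 0.073). The difference passed without mesoderm replicate 2 (-1.23, adjusted p = 0.035) and with array weights (adjusted p = 0.034). Over the other 5 arrays left out its adjusted p was 0.0909 to 0.21. In the list of TWIST1 and its bHLH and Id partners 2 of 10 members were higher in crest and 0 in mesoderm (2 and 0 adjusted over the list alone), with a median of -0.66 (adjusted p = 0.00831, adjusted p = 0.119 with an estimated correlation). Without mesoderm replicate 2 the crest count was 4. The 2 genes were Tal2, a bHLH gene of the midbrain, at -3.12 ± 0.37, and Tcf3, an E protein gene, at -1.32 ± 0.22. Id2, an inhibitor of bHLH factors, differed by -1.28 ± 0.47 (adjusted p = 0.0973, but 0.0441 under median scaling), with 1 other probe in the opposite direction. Among 15 regulators of mesenchyme and epithelial-mesenchymal transition 2 were higher in each sort (2 in mesoderm and 3 in crest adjusted over the list alone), with a median of 0.14 (adjusted p = 0.538). The receptor gene Tgfbr2 was higher in mesoderm by 2.54 ± 0.31 and its ligand gene Tgfb1 at least 1.77-fold. In crest the cadherin gene Cdh6 differed by -3.07 ± 0.28 and Sox4 by -0.87 ± 0.23, the latter call lost on leaving out any array but mesoderm replicate 2 (adjusted p up to 0.108). The mesoderm count of these regulators was 1 without any 1 of the mesoderm arrays, where Tgfb1 was no longer tested. The mesenchyme gene Prrx1 differed by 0.12 ± 0.42 (adjusted p = 0.884), with both other probes and median scaling giving the opposite sign, and Specc1l, a cytoskeletal gene of facial clefts, by -0.46 ± 0.31 (adjusted p = 0.347), with -0.71 without crest replicate 1, -0.22 without crest replicate 2 and -0.25 without mesoderm replicate 1. Frontonasal genes had 2 of 8 higher in each sort (2 in mesoderm and 3 in crest adjusted over the list alone), with a median of 0.31 (adjusted p = 0.622). Their mesoderm count was 0, 1 and 1 without mesoderm replicates 1, 2 and 3 and 1 without crest replicate 3, and their crest count 1 without crest replicate 1, 2 or 3 or mesoderm replicate 1. Foxd1 was at least 4.51-fold higher in mesoderm and Tfap2c lower at -2.22 ± 0.42. Alx4 at 1.24 ± 0.30 and Alx1 at -1.13 ± 0.32 parted, but the first call was lost without crest replicate 3, mesoderm replicate 1 or mesoderm replicate 3 (adjusted p up to 0.0944) and the second on leaving out any array but mesoderm replicate 3 (up to 0.134).

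Among signalling pathways FGF genes were higher in crest. Of 10 tested, 3 were higher there and 0 in mesoderm (3 and 0 adjusted over the list alone), with a median of -0.67 (adjusted p = 0.00331, adjusted p = 0.218 with an estimated correlation). Fgf8, the ligand gene of the midbrain-hindbrain boundary, differed by -3.48 ± 0.34, and the FGF antagonist gene Il17rd by -2.46 ± 0.22. Etv5, a target of FGF signals, differed by -1.84 ± 0.46, its call lost without crest replicate 2 or 3 or mesoderm replicate 1 or 3 (adjusted p up to 0.0804). Hedgehog genes gave 2 of 6 higher in crest and 0 in mesoderm (3 and 0 adjusted over the list alone), with a median of -0.73 (adjusted p = 0.0181, adjusted p = 0.232 with an estimated correlation). The list's call was also lost with no filter (median -0.18, adjusted p = 0.104) and with the mean of a gene's probes (median -0.53, adjusted p = 0.0791). The 2 genes were the receptors Cdon at -2.04 ± 0.28 and Ptch1 at -1.18 ± 0.23, while Sufu, at -0.76 ± 0.26 (adjusted p = 0.0732, but 0.0422 without mesoderm replicate 3, 0.0394 under median scaling and 0.00771 with array weights), had 1 other probe in the opposite direction. WNT genes were split, 7 of 22 being higher in crest and 3 in mesoderm (10 and 3 adjusted over the list alone), with a median of -0.77 (adjusted p = 0.0287, adjusted p = 0.446 with an estimated correlation). The ligand gene Wnt4 was at least 2.63-fold higher in crest, and Sp8, a zinc finger gene, differed by -1.13 ± 0.21 and Sfrp2, a secreted inhibitor, by -1.02 ± 0.22. Rspo3, an enhancer of WNT signals, Frzb, a secreted inhibitor, and Dkk3, of the Dickkopf family, were higher in mesoderm by 1.13 ± 0.32, 1.11 ± 0.26 and 0.98 ± 0.22. The list's call was lost under median scaling (median -1.08), with members detected in both groups (-0.70) and without crest replicate 2, crest replicate 3, mesoderm replicate 1 or mesoderm replicate 3 (medians -0.71, -0.67, -0.56 and -0.67). Its crest count was 4, 3 and 1 without crest replicates 1, 2 and 3 and 4 without mesoderm replicate 1 or 3. Calls were also lost on leaving out 1 array for Rspo3 (any array but mesoderm replicate 3, adjusted p up to 0.131), Frzb (crest replicate 2 or 3, mesoderm replicate 1 or 3, up to 0.0991), Dkk3 (crest replicate 1 or 3, up to 0.0675) and Sfrp2 (crest replicate 3 or mesoderm replicate 1, up to 0.0704).

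BMP and TGF-beta genes did not shift as a list, with 3 of 15 higher in mesoderm and 0 in crest (4 and 0 adjusted over the list alone). Their median was -0.05 while their mean was 0.32 and camera's direction was toward mesoderm (adjusted p = 0.495). The members that rose in mesoderm were the ligand genes Bmp4 by 2.97 ± 0.35 and Gdf10 by 1.75 ± 0.27 and the coreceptor gene Tgfbr3 by 1.39 ± 0.22. Notch genes went both ways, 2 of 8 higher in mesoderm and 1 in crest (2 and 1 adjusted over the list alone), with a median of -0.52 (adjusted p = 0.825). Notch4, an endothelial receptor gene, was higher in mesoderm by 2.27 ± 0.24, as was the glycosyltransferase gene Mfng by 1.69 ± 0.37, a call lost without mesoderm replicate 1 (adjusted p = 0.0647). The ubiquitin ligase gene Dtx4 differed by -3.04 ± 0.30. In the retinoic acid pathway 2 of 5 were higher in mesoderm and 1 in crest (2 and 1 adjusted over the list alone), with a median of 0.30 (adjusted p = 0.266). The mesoderm count was 0, 1 and 0 without mesoderm replicates 1, 2 and 3 and 1 without crest replicate 1 or 3. Cyp26a1, which degrades retinoic acid, was at least 4.39-fold higher in mesoderm and the binding protein gene Crabp2 lower at -1.57 ± 0.30, while the receptor gene Rarb, at 1.02 ± 0.27, lost its call without crest replicate 1 or 3 or mesoderm replicate 1 or 3 (adjusted p up to 0.135). Guidance genes gave 3 of 23 higher in each sort (4 in mesoderm and 3 in crest adjusted over the list alone), with a median of 0.11 (adjusted p = 0.735). The semaphorin receptor genes Plxnd1 and Nrp1, both of endothelium, were higher in mesoderm by 4.79 ± 0.32 and 1.71 ± 0.27, and Ephb1 and Slit2 differed by -2.90 ± 0.49 and -1.38 ± 0.23.

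The remaining lists did not pass. Of 5 tested endoderm genes 1 was higher in mesoderm and 3 in crest (1 and 3 adjusted over the list alone), with a median of -2.03 (-1.34 with 2 at their bound, adjusted p = 0.186). Hhex, also a gene of endothelial and blood progenitors, was higher in mesoderm by 3.93 ± 0.24, and Sox21, Shh (at least 7.12-fold) and Foxa1 (at least 2.53-fold), which the neural tube also expresses, were higher in crest. The crest count was 1 without any 1 of the crest arrays. Of 8 genes of surface ectoderm 1 was higher in crest and 0 in mesoderm (1 and 0 adjusted over the list alone), with a median of -0.12 (adjusted p = 0.212). The count was 2 without mesoderm replicate 3. The gene past the threshold was the protease inhibitor gene Spint1 at -2.94 ± 0.41, while the keratin gene Krt8 differed by -0.61 ± 0.20 (adjusted p = 0.0726, but 0.0218 with no filter, 0.0382 without background correction, 0.0403 with the authors' values and 0.0345 with array weights). Cell cycle genes had 1 of 24 higher in crest and 0 in mesoderm (1 and 0 adjusted over the list alone), with a median of -0.21 (adjusted p = 0.212, but 0.0282 without crest replicate 1). It was the cyclin gene Ccne1 at -1.72 ± 0.36, a call lost without crest replicate 3 (adjusted p = 0.0641), and the count was 3 without crest replicate 1 and 2 without mesoderm replicate 2. Glycolysis and hypoxia genes had 2 of 17 higher in crest and 0 in mesoderm (5 and 2 adjusted over the list alone), with a median of -0.13 (adjusted p = 0.508). Without crest replicate 2 or mesoderm replicate 2, 1 was higher in mesoderm. The 2 higher in crest were Pfkl at -0.90 ± 0.25 and Pgk1 at -0.85 ± 0.22, glycolytic enzymes, with calls lost on leaving out any array but mesoderm replicate 3 for the first (adjusted p up to 0.138) and any but mesoderm replicate 2 for the second (up to 0.114). Of 4 Hox and Meis genes 0 passed by limma (1 higher in crest adjusted over the list alone), with a median of -0.68 (adjusted p = 0.311), Meis2 having the largest difference at -1.11 ± 0.34 (adjusted p = 0.0537, but 0.0121 without mesoderm replicate 2, 0.0125 with array weights, 0.0296 with trend and robust fitting and 0.048 with the stricter filter). Among 3 sex-linked transcripts, too few for a list test, Xist, the noncoding RNA of the inactive X chromosome, was higher in crest at -2.01 ± 0.53 (1 of 3 adjusted over the list alone), a call lost without crest replicate 1 or 2 or mesoderm replicate 1 or 3 (adjusted p up to 0.113). The Y-linked Eif2s3y differed by 1.37 ± 0.57 (adjusted p = 0.131, but 0.0369 without crest replicate 1).

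**Figure D3:**
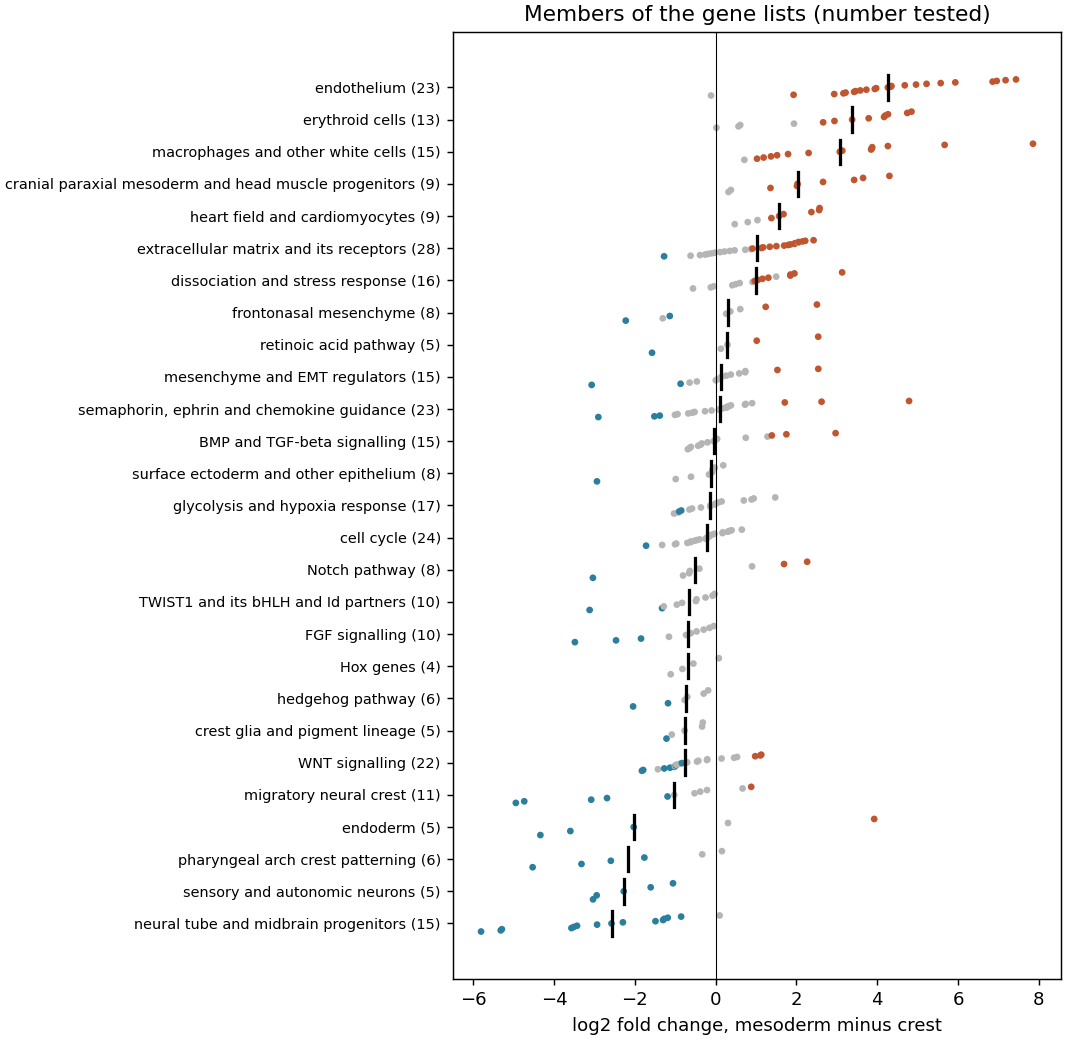
Log2 difference, mesoderm minus crest (x), of each tested member of the 27 lists tested (y), 1 point per gene, coloured where the adjusted p was under 0.05. The black bar is the median of a list, from 4.26 in endothelium to -2.58 in the neural tube list.

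The 5 lists that held with an estimated correlation were endothelium, macrophages and other white cells, cranial paraxial mesoderm, heart field, and neural tube, each at an adjusted p of 0.047, of 16 past the threshold with the preset correlation. Of the 103 named genes past the threshold, 83 stayed past it in every fit with 1 array left out in which they could be tested. Of the 103, 15 lost their call with no filter, 12 under median scaling, 11 without background correction, 10 with the authors' values, 5 with an offset of 50 and 3 with the mean of a gene's probes. Beyond genes already described as losing a call, these were Stmn2 and Tfap2c with no filter, Tgfbr3 under median scaling and Slit2 with the mean of a gene's probes and with matching probes only. Of the 29 named genes not past the threshold, 14 passed with array weights, 6 without background correction, 6 with the authors' values, 4 with an offset of 50, 4 with trend and robust fitting, 3 with no filter, 3 with the mean of a gene's probes, 2 under median scaling and 1 with the stricter filter. With the deposited detection p, an alternative chosen after the data were seen, 66 of the 103 lost their call, among them Sox10 (adjusted p = 0.105), Wnt1 (0.11) and Tfap2a (0.9), and 2 of the 29 passed. Median scaling moved the median difference of all genes from -0.07 to -0.30, a shift toward crest to which small differences are relative.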

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

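The alternatives with the deposited detection p, with only probes whose deposited p went with their signal, and with both replicate 2 arrays left out were chosen after the data were seen; the others were fixed before. The 5 lists named in the report as holding with an estimated correlation (endothelium, white cells, cranial paraxial mesoderm, heart field and neural tube) kept their direction and their call under each alternative that gave a value. The counts of 935 and 767 genes stayed within 1.5 times under no background correction (852 and 684), an offset of 50 (905 and 730), the authors' values (858 and 688), no filter (752 and 532 of 19053 genes), the stricter filter (895 and 767), the mean of a gene's probes (953 and 815), trend and robust fitting (990 and 866), a minimum of 2-fold (810 and 552) and matching probes only (730 and 599 of 7616). The replicate numbers did not pair the arrays throughout. Deviations from the group mean correlated across genes at 0.118, 0.323 and 0.017 for equal numbers. Crest 1 went more with mesoderm 3 (0.207) and crest 3 more with mesoderm 1 (0.087). Crest 2 went most with mesoderm 2 (0.323), the highest value across groups, so a pairing of the replicate 2 arrays cannot be excluded. With the replicate block the counts were 1046 and 937, all 27 lists kept their call, 6 named genes gained a call and 2 lost it, and Twist1 passed (adjusted p = 0.0206, against 0.0206 to 0.24 over its alternatives).

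Under median scaling the counts were 596 for mesoderm and 726 for crest, and under array weights 1310 and 1470, so both settings, as well as the fits without mesoderm replicate 2 (649 and 735) or 3 (561 and 575), gave more genes to crest, the reverse of 935 and 767. With array weights crest replicate 3 had a weight of 6.21 and the others 0.442 to 1.23. An adjusted p under 0.01 gave 575 and 277. With 1 array left out, and so with less power, the counts ranged from 433 to 762 for mesoderm and from 241 to 735 for crest. With both replicate 2 arrays left out they were 465 and 334 of 8210 genes, but 794 and 592 when the same 9218 genes were tested, so much of that loss came from the filter, which then asks for 3 of 4 arrays. The deposited p gave 231 and 172 and took the call from 66 of the 103 named genes past the threshold, since it put the fitted background mean between 439 and 817 intensity units, against 97 to 124. Signal over background limits the rest: 270 tested genes were detected on no crest array and 160 on no mesoderm array.

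With an estimated correlation the medians do not change but the call was lost for erythroid cells (3.379), ECM (1.027), dissociation (1.008), sensory neurons (-2.272), pharyngeal arch (-2.177), migratory crest (-1.022), FGF (-0.671), TWIST1 partners (-0.656), hedgehog (-0.732), WNT (-0.767) and glia and pigment (-0.766). fry, which tests a list by itself, called endoderm (-2.026), frontonasal (0.314), retinoic acid (0.295) and surface ectoderm (-0.123) as well. The glia and pigment list, of 5 genes, also lost its call under no background correction (-0.419), an offset of 50 (-0.654), median scaling (-0.957), the authors' values (-0.469), the mean of a gene's probes (-0.766), members detected in both groups (-0.55), matching probes only (-0.55), the deposited p (0) and both replicate 2 arrays left out with the same genes (-0.697), with adjusted p between 4.52e-04 and 0.176 over its alternatives. WNT lost its call under median scaling (-1.076) and with members detected in both groups (-0.701), with adjusted p between 0.0065 and 0.446. Hedgehog lost it with the mean of a gene's probes (-0.532) and no filter (-0.176), and hedgehog and migratory crest with the deposited p (medians 0). Lists not past the threshold changed camera's direction in these cases: frontonasal with members detected in both groups (0.262), matching probes (-0.696) and the deposited p (0), Notch with the stricter filter (-0.401) and Hox with no filter (0.028). With 1 array left out it also changed for frontonasal without mesoderm replicate 1 or 2, for Notch without crest replicate 1 or 3 or mesoderm replicate 2 or 3, and for guidance without crest replicate 2, although the medians of frontonasal and Notch kept their sign. With 1 array left out the medians ranged from -0.9 to -0.563 for WNT, -0.976 to -0.564 for glia and pigment and -0.323 to -0.179 for cell cycle (past the threshold without crest replicate 1). For lists not past the threshold in any of these fits they ranged from -0.272 to -0.022 for glycolysis, -0.245 to -0.116 for surface ectoderm, -1.1 to -0.416 for Hox and 0.109 to 0.289 for mesenchyme and EMT regulators. They ranged from 0.133 to 0.37 for frontonasal, -0.619 to -0.269 for Notch and -0.076 to 0.257 for guidance. The sign changed for genes not past the threshold: Prrx1 (-0.236 under median scaling, -0.102 as the mean of probes, -0.166 to 0.631 with 1 array left out), Meis1 (-0.257, -0.686, and -0.058 to 0.265) and Kdr (-0.281 to 0.067). Except where a cause is given above, the cause was not tested. Lists with fewer than 4 tested members under an alternative, such as 6 of 27 with both replicate 2 arrays left out, gave no value there.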

Other observations

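The tests of histones by cell cycle, of globins and other red cell genes and of dilution were chosen after the results they concern were seen. So were the histone values of mesoderm replicate 2, the number of genes in other splits and the genes of the next 2 paragraphs. The test of lists in other splits was written before. That of polyadenylated histones was written before its own values were seen. It does not count as planned, since it concerns low histones on crest replicate 2. Histones were not among the 28 lists fixed in advance.

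Outside the rule, single genes with large differences toward mesoderm are given here by value, without a count of how many genes of their kind did not differ. The platelet and megakaryocyte genes Gp5, Gp9, Gp1bb and Tubb1 were at least 38.9-fold, 33.9-fold, 18.5-fold and 35.0-fold higher than in crest, and Vwf, of platelets and endothelium, at least 15.2-fold. Mpo and Prtn3, proteins of myeloid granules, were at least 43.6-fold higher and higher by 4.62 ± 0.22 on the log2 scale (SE, n = 3 per group). Gata2, Lyl1 and Gfi1b, factor genes of blood progenitors, were higher by 3.30 ± 0.31, at least 14.9-fold and at least 14.8-fold. The endothelial nitric oxide synthase gene Nos3 rose by 3.91 ± 0.25, the flow-responsive factor gene Klf2 at least 15.5-fold and the arterial connexin gene Gja4 at least 20.3-fold. The growth factor gene Igf1 was higher by 4.33 ± 0.26 and the smooth muscle actin gene Acta2 by 3.40 ± 0.43.

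Single genes toward crest were picked likewise. Otx1 and Pou3f1, factor genes of the anterior neural tube, differed by -3.20 ± 0.22 and -3.19 ± 0.41, and Fgf17, a ligand gene of the midbrain-hindbrain boundary, was at least 10.2-fold higher in crest. Lhx5 was at least 3.88-fold higher and Wnt7a at least 3.40-fold. Insm1 and Myt1, factor genes of differentiating neurons, differed by -2.82 ± 0.33 and -2.73 ± 0.31, the axonal motor gene Kif1a by -3.16 ± 0.37, the microtubule gene Map2 by -2.58 ± 0.35 and the adhesion gene Nrcam by -2.22 ± 0.22. The RNA-binding Msi1, of neural progenitors, differed by -1.76 ± 0.36. B3gat1, which makes the HNK-1 epitope of crest and neurons, differed by -3.90 ± 0.46.

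With 10 splits of the 6 arrays into 3 and 3 no share under 0.05 can be reached. The real split gave 1702 genes past the threshold and the highest other split 0, so 1 of 10 gave as many. It gave 16 lists, and the highest other split, crest replicates 1 and 3 with mesoderm replicate 2, gave 12 lists with 0 genes, so again 1 of 10 gave as many. Each other split still holds more crest arrays on one side, so part of the cell type difference remains in it. Lists called there with the preset correlation of 0.01 therefore do not show whether that correlation was too low.

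Both replicate 2 arrays were low in histones, crest replicate 2 most. Of 51 replication-dependent histone genes tested, 49 were lower on crest replicate 2 than on both other crest arrays, with a median difference of -1.74, and 40 on mesoderm replicate 2 than on both other mesoderm arrays, with a median of -0.67, while Rnu6, a small RNA without a poly(A) tail, differed by -2.91 and -1.41. Fewer cycling cells would lower the cell cycle list as well. Its 24 members instead lay higher on crest replicate 2 by 0.363 ± 0.117 (SE over genes). That SE treats the genes as independent, although their estimated correlation was 0.189, and it rests on 1 array. The value therefore does not decide, and no other biological explanation was tested. Histone variants with a poly(A) tail differed on crest replicate 2 by a median of -0.174 (SD 0.65, 8 genes), in line with less carry-over of transcripts without a tail. One of them, H2az2, fell by 1.72, as far as the median of the replication-dependent genes, and less carry-over would not account for it.

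Globin transcripts were abundant on crest replicates 1 and 3, although the sort for GFP would leave out unlabelled red cells. From the mesoderm mean they fell by 1.94 on crest replicate 1 and by 2.86 on crest replicate 3 (log2, mean of 4 globin genes), with Hbb-bh1 at 11.28 and 10.46 there. Over the 4 genes the larger SD of the drop was 0.339, as RNA of red cells of one make-up in both sorts would give. Red cells within the crest sort would give this as well as carried-over red cell RNA, so the SD does not tell these apart. Carried-over RNA remains a candidate source of the globins. Of the 9 other red cell genes tested, Lmo2, Nfe2 and Tal1 fell further on both arrays (Lmo2 by 4.86 and by 4.85), Slc4a1, Klf1, Epor and Rhag less on both (Slc4a1 by 1.08 and by 1.77), and Alas2 and Cited4 further on crest replicate 1 and less on crest replicate 3. Other cells express some of them and Nfe2, Tal1 and Alas2 were detected on no crest array, so they do not decide, and the source stays open, as does whether the red cells of the mesoderm sort were themselves labelled.

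The list of TWIST1 and its partners had a median of -0.66, with 2 of 10 members past the threshold and its call lost with an estimated correlation (adjusted p = 0.119, against 2.53e-04 to 0.119 over its alternatives). If there is a shift toward crest, it may reflect dilution of mesenchyme by the blood and endothelium in the mesoderm sort. Dilution would lower other mesenchyme genes alike, yet the 15 mesenchyme and EMT regulators had a median of 0.141 (SD 1.224, 0.109 to 0.289 with 1 array left out). Since they went both ways and endothelium expresses some of them, such as Tgfbr2, that median does not decide. Dilution and a difference between the mesenchyme cells themselves cannot be told apart on bulk arrays. The shift need not lie in mesenchyme alone. Tal2, 1 of the 2 members past the threshold, is a midbrain gene and differed by -3.12. Of 15 neural tube genes 14 were higher in crest, and the part of neural tube cells in the shift was not tested.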
